A study of Homo sapiens with 10 samples.

How the data were processed

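Libraries came from SRA01-04 cells, 5 with the empty vector and 5 with the RORα plasmid, all with 10 µM selenite for 24 h. The labels describe total RNA extracted with TRIzol, selection on poly-T beads and random hexamer priming. They name no step that marks the strand, so reads of overlapping genes on opposite strands cannot be told apart. The submitters' processing notes name HISAT2 2.2.1 for alignment to GRCh38 and HTSeq for counting, and the annotation release is not given in the sources used here.

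The deposited table held 12540 genes, each with raw read counts and FPKM per library, per the file headers. The counts were whole numbers. The FPKM values that the authors deposited equalled the count divided by the column's own count total and by 1 length per gene, with totals matching to a relative difference of 2.5e-05. That length had a median ratio of 1.001 to the summed exon length over all annotated transcripts of a gene and of 2.598 to the union of its exons, so FPKM was compared only between libraries and not between genes. The lowest total of any gene over the 10 libraries was 88 counts, and how the table was reduced to these genes is not stated, so a gene missing from it is not shown to be unexpressed. Gene IDs were matched to GENCODE 29, which gave positions and overlaps for 12528 of them. The other 12, among them that of SOD2, had no match, and 12511 of those matched were protein-coding. Of 1138 genes in the gene lists, 942 were in the table.

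Group, dose and time came from the sample labels. The tests, alternatives, naming rule and gene lists were fixed before the data were examined. They assumed a table of FPKM only, with limma as the test, and stated that edgeR on counts would be the test if counts were present. Counts were present, so edgeR gave every gene's result and the limma fits on FPKM became alternatives. Genes passed filterByExpr (count of at least 10, total of at least 15), which kept 12520 and left out 20. Counts were scaled with TMM factors, which lay between 0.991 and 1.006, and fitted by edgeR 4.0.16 (estimateDisp, glmQLFit, glmQLFTest, two-sided) in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. CPM values used TMM-scaled totals. For genes with 10 or fewer counts in a group, the ratio of summed counts has an exact conditional binomial interval at 95%. RORA was also compared by an exact two-sided permutation test. Library totals ran from 17475342 to 21956761 counts, so 3 counts, the limit of a count of 0, equal 0.137 to 0.172 CPM. Intervals and limits cover counting error only, since reads carried no molecular identifiers.

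Gene lists were tested by camera in limma 3.58.1 on log2(FPKM + 1) of the 8445 genes with a mean FPKM of at least 1, with an inter-gene correlation of 0.01, for lists with at least 5 genes kept. The counts of members that rose or fell come from edgeR, so they cover more genes than the list test. For some lists that test held only part of them, such as 9 of 16 clock genes and 7 of 13 epithelial genes. Camera was repeated with the correlation estimated per list, negative estimates being set to 0, and fry was run on the same values. With an estimate, camera also uses fewer degrees of freedom, so a call lost in that setting need not be due to correlation. The G1/S list had an estimate of 0.01, the preset value, yet its unadjusted camera p went from 0.0188 to 0.047.

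Genes were named by this rule: RORA, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, and from each of 29 lists described, up to 4 members past the threshold by size of change. Genes without a symbol were not named. This gave 127 genes, and any other gene is said to have been chosen after its values were seen.

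Alternatives were DESeq2 1.42.0 and its size factors, no count filter, the replicate number as a block, leaving out each library, and limma on FPKM with pseudocounts of 1, 0.1 and 0.01 and mean FPKM filters of 1, 0.1, 5 or none. Further limma alternatives were rescaling to TPM or by median ratio, quantile normalization, no trend, a robust fit, array weights and an exact rank-sum test. The labels do not say whether replicate numbers pair the libraries. Same-number correlations of residuals lay between -0.09 and 0.09, so the libraries were treated as unpaired, although such values cannot show that they were. No 2 replicates were copies: over 20 pairs within groups, the chi-square per degree of freedom lay between 2.27 and 5.73. GC content and exon length trends were removed with splines of 4 degrees of freedom over 12483 genes. The edgeR test was tested on simulated data, drawn independently for each gene, in which 200 of 12530 genes were changed. It recovered 22% of 50 genes at 1.1-fold, 84% of 50 at 1.25-fold, 82% of 50 at 1.5-fold and 90% of 50 at 2-fold. Of its 146 calls, 4.8% were false. Far fewer genes changed there than the 56.1% called in the data, so these rates need not hold for the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.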

Results

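Messenger RNA was sequenced from SRA01-04 cells, a human lens epithelial line immortalised with a viral large T antigen. The cells carried either a plasmid expressing RORα, the nuclear receptor encoded by RORA, or the empty plasmid. From 48 h after transfection both groups received 10 µM selenite, a selenium salt that oxidises thiols and causes cataract in young rodents, and they were collected after 24 h of it. The 2 groups held 5 libraries each, called EV1 to EV5 for the empty vector and OE1 to OE5 for RORα overexpression. No group lacked selenite or transfection, so the values below describe selenite-treated cells only. The library totals were 18427671, 20028842, 20356469, 17653948 and 19647271 counts for EV1 to EV5, and 21956761, 21120821, 18276861, 17475342 and 19610853 for OE1 to OE5. A count of 0 in a library allowed a level of up to 0.137 to 0.172 CPM (counts scaled to a library total of 1e6), which covers counting error only. The labels do not say whether replicates were separate cultures, so every p-value measures only the spread between these samples.

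The 1 comparison that the labels give, RORα overexpression minus empty vector, asks which transcripts differ in selenite-treated lens cells when RORα is overexpressed. Most of the inflammatory cytokine genes listed rose, as did target genes of the integrated stress response and genes of antigen presentation. Fibroblast marker genes, among them the collagen genes COL3A1, COL1A2 and COL1A1, fell. CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716), a neutrophil-attracting chemokine, rose 10.8-fold, from 54.3 ± 3.16 to 585 ± 36.1 CPM (SD, n = 5 per group; edgeR adjusted p = 3.03e-40). COL3A1 (ENSG00000168542, chromosome 2, 188974320 to 189012746), a fibrillar collagen of soft connective tissue, fell from 116 ± 2.68 to 8.91 ± 0.677 CPM (13-fold lower, edgeR adjusted p = 8.75e-38). AKR1B1 (ENSG00000085662, chromosome 7, 134442350 to 134459284), aldose reductase, which makes sorbitol from glucose and is long studied in sugar cataract, was chosen after its values were seen: it fell from 2017 ± 51.5 to 509.5 ± 16.3 CPM (3.96-fold lower, edgeR adjusted p = 8.56e-39). Of 12520 genes tested, 7026 (56.1%) passed a Benjamini-Hochberg adjusted p of 0.05 in the edgeR quasi-likelihood test, 3581 higher and 3445 lower. Of these differences, 3028 were under 1.2-fold, 3369 lay between 1.2-fold and 2-fold, and 629 reached 2-fold, 411 of them higher and 218 lower. All 5 overexpression values lay above all 5 empty vector values for 2598 genes and below them for 2361, together 39.6% of genes against 0.79% by chance. Replicates differed little, with a biological coefficient of variation of 4.6%. An alternative that changed test, filter and scale together, limma on log2(FPKM + 1) of 8445 genes, counted 131 genes at 2-fold in place of 629, and 246 with a pseudocount of 0.01.

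RORA itself (ENSG00000069667, chromosome 15, 60488284 to 61229319, minus strand, GRCh38) rose 2.74-fold, from 15 ± 2.29 to 41.3 ± 2.21 CPM (SD, n = 5 per group). The log2 fold change was 1.46 with a standard error of 0.073 (edgeR adjusted p = 4.35e-20). The highest empty vector library stood at 17 CPM and the lowest overexpression library at 38.6 CPM. An exact two-sided permutation test of 5 against 5 libraries gave p = 0.0079, the smallest that this many libraries allow. On log2(FPKM + 1) the difference was 0.73, since the added 1 is large against its FPKM. Gene-level counts do not separate plasmid transcripts from those of the chromosomal gene.

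**Figure D1:**
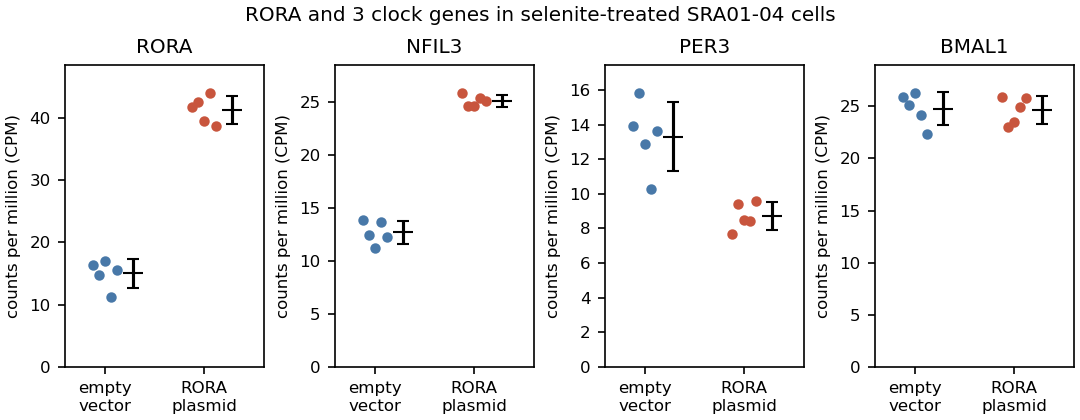
CPM of RORA, NFIL3, PER3 and BMAL1 in each of the 5 empty vector libraries (blue) and 5 RORα plasmid libraries (red), on linear axes that start at 0. Bars give the mean and SD of each group; RORA and NFIL3 sat higher in every RORα library, PER3 sat lower, and BMAL1 overlapped.

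Circadian clock genes, several of which carry RORα response elements in their promoters, moved in both directions. Of 16 clock genes tested, 8 rose, 4 fell and 4 did not pass, with 8 rises and 4 falls adjusted over the list alone. BHLHE41, a repressor of CLOCK and BMAL1, had a log2 fold change of 1.41 (3.16 to 8.39 CPM), NFIL3, a repressor that competes with DBP for D-box sites, 0.99 (12.7 to 25.1 CPM), and PER2 0.62. PER3 fell by 0.61 on the log2 scale, from 13.3 to 8.72 CPM. Of members chosen after their values were seen, NR1D1, a repressor that shares its response element with RORα, rose by 0.56, and CLOCK fell by 0.36. BMAL1, the best known RORα target of the clock, stood at 24.8 and 24.6 CPM (log2 fold change -0.01, edgeR adjusted p = 0.919). The median over the list was 0.09 and the list did not pass (limma camera adjusted p = 0.308). Of 9 genes named as RORα targets in other tissues, 7 of lipid metabolism beside NFKBIA and SOX4, 4 rose, 3 fell and 2 did not pass, with the same counts adjusted over the list alone. ABCA1, a cholesterol exporter, fell by 1.31 on the log2 scale (38.5 to 15.6 CPM) and FASN, fatty acid synthase, by 0.51. NFKBIA, the NF-kB inhibitor, which is also in the NF-kB list below, rose by 0.87 and PLIN2, a lipid droplet coat protein, by 0.22. Without NFKBIA 3 rose and 3 fell, with a median of 0.01. The median of the whole list was 0.05 and its mean -0.06, and camera, whose direction was up on FPKM and down on CPM, gave an adjusted p of 0.728.

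Most genes of the NF-kB list, cytokines and chemokines together with NF-kB regulators and other targets, rose. Of 33 members tested, 30 rose, 24 of them at least 2-fold, 1 fell and 2 did not pass, with 30 rises and 2 falls adjusted over the list alone. CSF3, the granulocyte growth factor, went from 0.225 to 8.97 CPM (log2 fold change 5.25), CXCL5 from 5.19 to 60.2 CPM (3.53), and CXCL3, like CXCL5 a neutrophil attractant, from 3.99 to 29.9 CPM (2.91). The members outside this pattern, all cytokine or chemokine genes, were chosen after their values were seen. IL11 fell by 0.38 on the log2 scale, TNF stood at 1.23 and 0.789 CPM (log2 fold change -0.63, edgeR adjusted p = 0.0511), and CCL2 at 20.4 and 22 CPM (0.10, edgeR adjusted p = 0.225). IL6, also chosen after its values were seen, rose from 23.4 to 111 CPM. The list's median was 1.69 (limma camera adjusted p = 2.48e-18, and 0.00025 with an estimated correlation). Of 11 inflammasome and pyroptosis genes, 9 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone, a median of 1.03 and a camera adjusted p of 0.00258. That camera test held 7 of the 11, without IL18 and CASP1. IL1B, the cytokine that caspase 1 matures, rose from 34.5 to 136 CPM, TXNIP, a thioredoxin inhibitor, from 8.08 to 31.3 CPM, IL18 from 1.98 to 5.50 CPM and CASP1 from 3.23 to 8.81 CPM. Of 26 genes of senescence and its secretory program, 16 rose, 4 fell and 6 did not pass, with the same counts adjusted over the list alone and a median of 0.68 (camera adjusted p = 0.000107). MMP10, a stromelysin, CXCL8, CXCL3 and CXCL2 had its largest rises, CXCL2 from 7.70 to 56.7 CPM. This list shares 8 genes with the NF-kB list, and of the other 18, 9 rose, 4 fell and 5 did not pass, with a median of 0.08.

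The 12 largest rises of the whole comparison also included genes outside these lists. ZP4, an egg coat glycoprotein, rose from 1.03 to 13.9 CPM, RCSD1, an actin-capping partner, from 0.774 to 9.91 CPM, and EHF, an epithelial ETS transcription factor, from 0.390 to 3.93 CPM. SERPINB2, plasminogen activator inhibitor type 2, had 2 counts in all empty vector libraries and 138 in the overexpression libraries, a ratio of 67.4 with a 95% counting interval of 18.3 to 562. Both of those counts came from EV3, and the fitted log2 fold change of 5.68 became 7.76 without it, a value that depends on the prior count. CCND2, cyclin D2, had 2 counts against 87 (ratio 42.5, interval 11.4 to 356), and part of its exons overlaps an antisense gene. MMP10 had 7 counts against 138 (ratio 19.2, interval 9.1 to 48.8), and its log2 fold change of 4.14 was 4.96 without EV1. CCL3L1 rose from 4.67 to 80.3 CPM, CCL4 from 0.347 to 3.43 CPM and CCL3 from 0.135 to 1.33 CPM. CCL3L1 is nearly identical to CCL3, CCL4 to CCL4L2, and CCL3 overlaps another annotated gene over 74.6% of its exons, so which of these copies rose is uncertain.

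**Figure D2:**
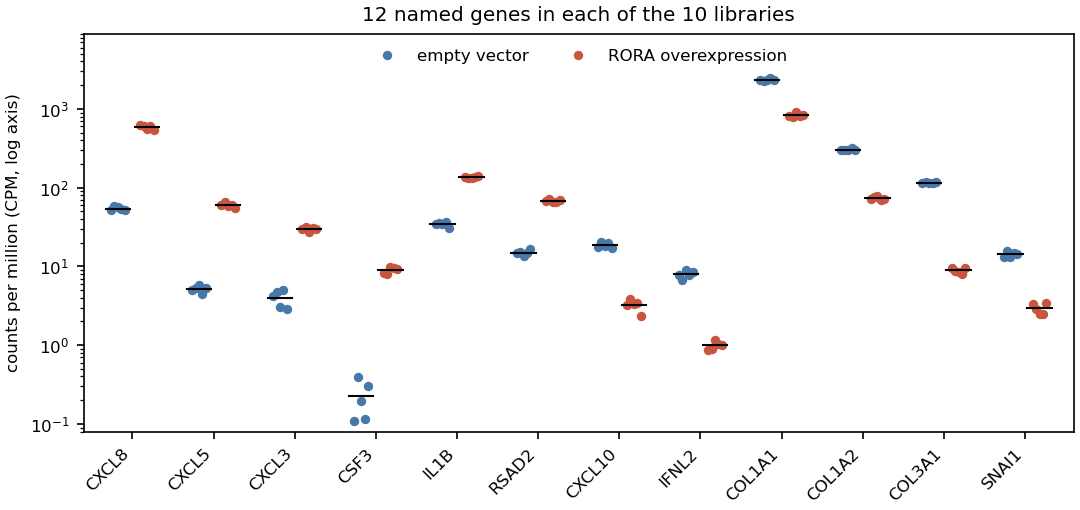
CPM (log axis) of 12 named genes in each of the 5 empty vector libraries (blue) and 5 RORα overexpression libraries (red), with a black bar at each group mean. No gene plotted has overlapping groups: CXCL8, CXCL5, CXCL3, CSF3, IL1B and RSAD2 sat higher with overexpression and CXCL10, IFNL2, COL1A1, COL1A2, COL3A1 and SNAI1 lower.

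Interferon-stimulated genes rose as a list, while 4 interferon genes and CXCL10 fell. Of 43 members tested, 31 rose, 7 fell and 5 did not pass, with 31 rises and 7 falls adjusted over the list alone. RSAD2, the antiviral enzyme viperin, rose from 15 to 68.1 CPM, IFI44L from 1.03 to 3.66 CPM and IFI44 from 66.2 to 175.5 CPM. CXCL10, a T cell attractant, fell from 18.6 ± 1.40 to 3.22 ± 0.545 CPM (5.76-fold lower, edgeR adjusted p = 1.23e-22). IFNL2, a type III interferon and one of the 12 largest falls, went from 7.94 to 0.991 CPM (8.02-fold lower). Its paralog IFNL3, chosen after its values were seen like the next 3 genes, fell from 6.07 to 0.905 CPM, and the near-identical sequences of this pair leave their single values uncertain. IFNB1 fell from 18.7 to 9.09 CPM, IFNL1 from 17.8 to 8.87 CPM and CXCL11 from 17.8 to 12.7 CPM. The list's median was 0.53 (limma camera adjusted p = 8.42e-05), and among genes with a mean FPKM of at least 5 its adjusted p was 0.0895. All 16 genes of antigen presentation tested, mostly of the class I pathway, rose, also adjusted over the list alone, with a median of 0.80 (camera adjusted p = 1.29e-07). HLA-B rose from 133 to 304.5 CPM and HLA-F from 3.30 to 8.47 CPM, both encoding class I heavy chains whose sequences resemble each other. The immunoproteasome subunits PSMB10 and PSMB9 rose from 2.08 to 4.69 CPM and from 16.1 to 32.9 CPM.

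Targets of ATF4 and CHOP, the transcription factors of the integrated stress response, rose almost without exception. Of 34 tested, 33 rose and 1 did not pass, with 33 rises adjusted over the list alone and a median of 0.74 (limma camera adjusted p = 1.44e-15). TRIB3, a pseudokinase induced by CHOP, rose from 54.7 to 188 CPM, SESN2, an amino acid sensor, from 28.9 to 88.9 CPM, STC2 from 210 to 644 CPM, and CHAC1, which degrades glutathione, from 16.3 to 46.8 CPM. SLC7A11, the cystine transporter, was the exception, chosen after its values were seen, with a log2 fold change of 0.00. ATF4, also chosen after its values were seen, rose from 253.5 to 391.5 CPM. A list of endoplasmic reticulum genes, holding chaperones and folding enzymes beside stress sensors and other stress genes, moved in both directions. Of 24 genes, 6 rose, 10 fell and 8 did not pass, with the same counts adjusted over the list alone. ERN1, the stress sensor IRE1, rose by 1.14 and XBP1, its substrate, by 0.62 on the log2 scale, while HSP90B1 fell by 0.50 and PDIA4 by 0.41. Their median was -0.06 and mean 0.01 with camera pointing down, and the list did not pass (camera adjusted p = 0.254).

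Genes of the p53 response and of apoptosis also rose as lists. Of 27 p53 target genes, 19 rose, 3 fell and 5 did not pass, with the same counts adjusted over the list alone and a median of 0.42 (limma camera adjusted p = 0.00014). SESN2 and GADD45A, a DNA damage response gene that rose from 76.8 to 235 CPM, stood first, followed by PMAIP1, which encodes the BH3-only protein NOXA (210 to 545 CPM), and CDKN1A, the inhibitor p21 (42.7 to 97.9 CPM). SESN2 and 1 other gene are also in the ATF4 list, and of the remaining 25, 17 rose and 3 fell. Large T antigen binds p53 in lines such as this. Of 40 core apoptosis genes, 24 rose, 2 fell and 14 did not pass, with the same counts adjusted over the list alone and a median of 0.38 (camera adjusted p = 0.000136). The apoptosis list shares 5 genes with the p53 list and 1 with the NF-kB list. Of the 35 outside the p53 list, 20 rose, 1 fell and 14 did not pass, with a median of 0.26. The largest rises came from both sides of the pathway: BCL2A1 (1.03 to 6.92 CPM) and BIRC3 (101 to 491 CPM) oppose cell death, and HRK (0.878 to 3.57 CPM) and BIK (0.306 to 1.14 CPM) promote it.

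Redox genes did not move as 1 group. Of 28 targets of NRF2, the regulator of antioxidant genes, 11 rose, 13 fell and 4 did not pass, with the same counts adjusted over the list alone and a median of -0.15 (limma camera adjusted p = 0.331). AKR1C3 fell from 6.49 to 1.81 CPM, AKR1C1 from 33.5 to 13.6 CPM and ME1, malic enzyme, from 181 to 68.6 CPM, while SQSTM1, the autophagy adaptor p62, rose from 333.5 to 618 CPM. The AKR1C paralogs are close in sequence, so their single values are uncertain. HMOX1 and NQO1, textbook NRF2 targets chosen after their values were seen, fell by 0.68 and 0.50 on the log2 scale. The antioxidant list of 27 genes held mostly enzymes, but its largest rise was that of TXNIP, the thioredoxin inhibitor. Of its genes, 13 rose, 5 fell and 9 did not pass, with the same counts adjusted over the list alone and a median of 0.18 (camera adjusted p = 0.0577). The antioxidant list passed, upward, in 7 of 25 alternative settings, whose adjusted p ran from 0.00152 to 0.537. SOD2, the mitochondrial superoxide dismutase and an NF-kB target, rose from 429 to 1316 CPM, GLRX from 6.53 to 15.2 CPM and GSTO1 from 104 to 173 CPM, beside TXNIP. Of 19 selenoprotein genes, whose products carry selenocysteine, 6 rose, 5 fell and 8 did not pass, with the same counts adjusted over the list alone and a median of 0.07 (camera adjusted p = 0.52). DIO2, a thyroid hormone deiodinase, fell from 8.22 to 3.06 CPM, and TXNRD1, thioredoxin reductase, rose from 918.5 to 1418 CPM and SELENOM from 46.3 to 71.5 CPM. GPX1 rose from 4.39 to 7.25 CPM with overlapping groups.

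Genes of the extracellular matrix and of mesenchymal cells fell. Of 43 mesenchymal and matrix genes, 7 rose, 27 fell and 9 did not pass, with the same counts adjusted over the list alone and a median of -0.33 (limma camera adjusted p = 1.91e-06). That call was lost at adjusted p = 0.0511 with an estimated correlation. Beside COL3A1, COL1A2 fell from 304 to 74.2 CPM and SNAI1, a transcription factor that represses E-cadherin, from 14.2 to 2.94 CPM. MMP9, a gelatinase, rose from 1.70 to 4.90 CPM. Members chosen after their values were seen were FN1, fibronectin, which fell from 5185 to 2287 CPM, TGFB1, which fell from 640 to 325 CPM, and VIM, vimentin, which rose from 1526 to 2065 CPM. Of 11 fibroblast markers tested, from 14 listed, none rose, 9 fell and 2 did not pass, with 9 falls adjusted over the list alone and a median of -1.22 (camera adjusted p = 3.08e-07). The camera test held 6 of the 11, among them COL3A1, COL1A2 and COL1A1. COL1A1 fell from 2347 to 829 CPM and PDGFRB, a growth factor receptor, from 231 to 82.5 CPM. The list shares 3 genes with the matrix list, and of the other 8, 6 fell and 2 did not pass. Few markers of other cell types were measured: 2 of 17 immune, 3 of 10 endothelial, 3 of 13 pigment cell or retina and 3 of 13 corneal markers. All 3 endothelial markers fell (median -0.57), as did 1 of the 2 immune markers (median -0.74), while 1 pigment cell or retina marker rose and 2 did not pass, and 1 corneal marker rose, 1 fell and 1 did not pass. Adjusted over the list alone these counts were the same except for 2 falls among immune markers. The highest empty vector levels among them, of genes chosen after their values were seen, were 2.98 CPM (CD14), 69.8 CPM (FLT1), 2.51 CPM (BEST1) and 3.41 CPM (MUC1).

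The 12 largest falls held further genes, of which only KRT3, a corneal keratin, was in a list given above. PRSS35, a serine protease homolog, fell from 113 to 15 CPM and PLCXD3 from 29.7 to 3.4 CPM. The remaining 8 lay at or below 2.67 CPM with the empty vector: CCDC102B, CCN4, PODN, PLPPR4, SUCNR1, HEPH, KRT3 and CACNA1H. Their log2 fold changes ran from -3.75 for CCDC102B to -2.84 for CACNA1H. CCN4, a secreted matrix-associated signalling protein, fell by 3.64 on the log2 scale and HEPH, a copper-dependent ferroxidase, by 2.96. Without OE3 the CCN4 value was -4.42, and without OE4 the HEPH value was -3.88.

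Epithelial and lens genes were mixed in direction. Of 25 epithelial junction and keratin genes listed, 13 were tested: 5 rose, 5 fell and 3 did not pass, with the same counts adjusted over the list alone. CLDN1, a tight junction claudin, rose from 51.0 to 215 CPM and OCLN, occludin, from 7.16 to 14.7 CPM. The partner keratins KRT8 and KRT18 fell from 904.5 to 264.5 CPM and from 242 to 69.6 CPM, and the annotation places these genes partly over each other. The list's median was 0.07 and its mean -0.02, with camera pointing down on FPKM and up on CPM (limma camera adjusted p = 0.728). Of 27 lens epithelium genes listed, 13 were tested: 3 rose, 6 fell and 4 did not pass, with the same counts adjusted over the list alone. Their median was 0.00 and their mean -0.31. Camera, which held 6 of them and not CRYAB, PDGFRA or COL4A4, gave an adjusted p of 0.124. The list passed, downward, in 2 of 24 alternative settings. CRYAB, the small heat shock protein αB-crystallin, fell from 1.43 to 0.370 CPM, PDGFRA from 2.90 to 1.24 CPM and the basement membrane collagen COL4A1 from 802 to 466 CPM, while COL4A4 rose from 1.23 to 2.37 CPM. PAX6, the eye field transcription factor, chosen after its values were seen, stood at 19.6 and 20.9 CPM (edgeR adjusted p = 0.284). Of 29 lens fibre genes listed, 10 were tested: 4 rose, 2 fell and 4 did not pass, with 5 rises and 2 falls adjusted over the list alone. Too few were kept for the list test on FPKM. Camera gave an adjusted p of 0.764, down, for the 7 kept by an FPKM filter of 0.1 and 0.826, up, for all 10 without a filter. On log2(CPM + 1), chosen after the data were seen, it gave 0.631, up. JAG1, a Notch ligand, fell by 0.80 on the log2 scale and BFSP1, a beaded filament protein, by 0.65. ANK2 rose by 0.78 and HSF4, a lens heat shock factor with overlapping groups here, by 0.68.

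Cell cycle genes fell slightly. Of 36 genes of the G2 and M phases, 3 rose, 27 fell and 6 did not pass, with the same counts adjusted over the list alone and a median of -0.17 (limma camera adjusted p = 0.000136). That call was lost at adjusted p = 0.141 with an estimated correlation. KIF20A, a mitotic kinesin, fell from 216 to 140 CPM, PLK1, a mitotic kinase, from 154.5 to 113 CPM, KIF23 from 243 to 179 CPM and CENPA, the centromere histone, from 60.0 to 44.6 CPM. Of 33 genes of the G1/S transition, 6 rose, 17 fell and 10 did not pass, with 6 rises and 18 falls adjusted over the list alone and a median of -0.11. Their camera adjusted p was 0.0452, and the call was lost in 5 of 25 alternative settings, among them at adjusted p = 0.135 with an estimated correlation. UHRF1 fell by 0.39 and CHAF1B by 0.34 on the log2 scale, while RPA2 rose by 0.50 and CDT1, a replication licensing factor, by 0.39.

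**Figure D3:**
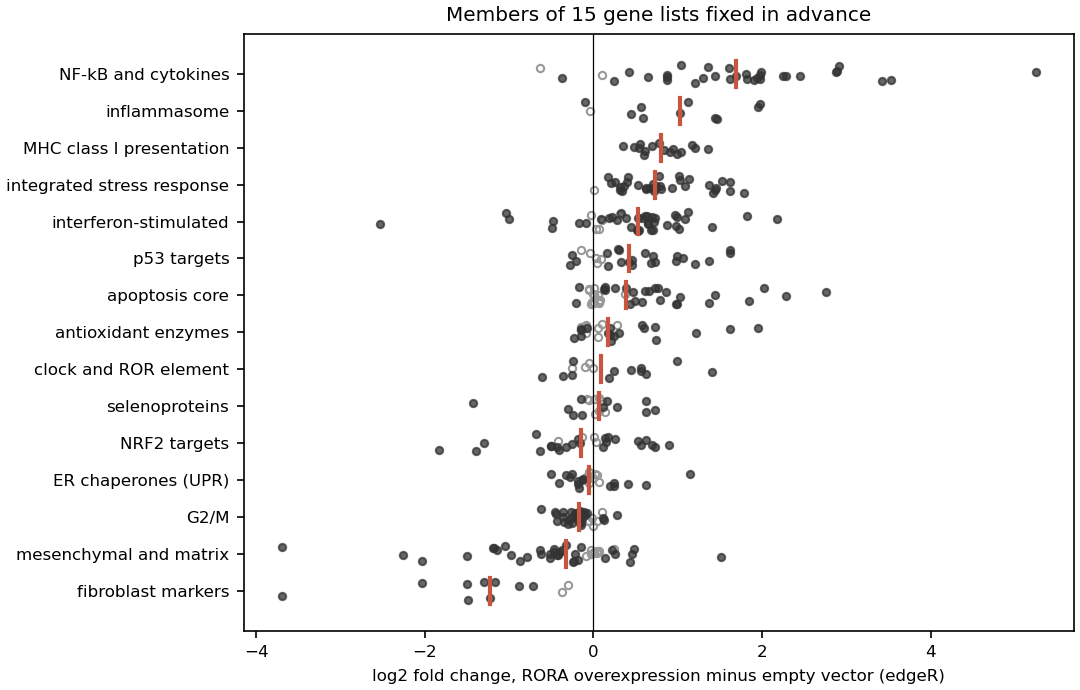
Log2 fold change (RORα overexpression minus empty vector, edgeR) of each tested member of 15 gene lists, with filled points for members with an adjusted p under 0.05, open points for the others and a red line at the median. The NF-kB list had the highest median of those plotted, 1.69, and the fibroblast markers the lowest, -1.22.

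Of the 43 lists, 36 had at least 5 genes kept for the list test, and 17 passed limma camera, 13 up and 4 down. Camera with an estimated correlation, which also uses fewer degrees of freedom, kept 9 of these calls. NF-kB, inflammasome, interferon, antigen presentation, senescence, ATF4, p53 and apoptosis passed up, with the highest adjusted p at 0.0408 for apoptosis. Fibroblast markers passed down at 0.0149. Camera compares a list with all other genes. The rotation test fry, which asks whether a list's genes move on balance in 1 direction and not whether they move more than others, passed 30 lists, and its mixed form, for changes in either direction, passed 36. Among the 127 genes named by rule, the groups did not overlap for 124 and overlapped for 3, GPX1, HSF4 and RPS27.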

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

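The tests of the NF-kB list against a shift of all genes alike, of mesenchymal cell content, of RORA against a mislabelled library and against scaling, of the whole matrix and fibroblast lists under the GC and length correction, and of other splits of the libraries were chosen only after the result was seen.

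For each named gene and for the library total, in each group of 5, the gap between the most extreme library and its neighbour was divided by the group's range (Dixon's ratio). It exceeded 0.71 in 17 of 256 groups, where chance gives about 1 in 20, or 5%. Among the empty vector libraries, EV2 was low for RPS23 (ratio 0.91) and HLA-B (0.793, 117 CPM against 134 to 138) and high for ME1 (0.85) and HSF4 (0.77). EV4 was low for IFI44 (0.856, 58.1 CPM against 67.6 to 69.1) and high for COL1A1 (0.783) and COL1A2 (0.711). EV1 was high for MMP10 (0.737), and EV3 held the only counts of SERPINB2 in its group (ratio 1). Among the overexpression libraries, OE3 was high for COL4A1 (0.852), CHAF1B (0.814) and SELENOM (0.761) and low for MT-CO3 (0.795). OE5 was high for RPA2 (0.757) and RPS23 (0.714), OE1 was low for ABCA1 (0.818), and OE2 was high for RPS27 (0.841, 135 CPM against 87.7 to 95.3). The first principal component, with 74.9% of the variance, separated the groups. On the second, with 5.1%, EV4 (-10.29), OE3 (-8.24) and OE5 (-5.3) lay lowest, and EV5 (-1.65) was the only other library below 0. After group means were removed, EV4 correlated at 0.189 with OE3 and 0.135 with OE5, the highest of 25 such pairs across groups. The labels name no batch that could be set against this, and leaving out EV4 and OE3 together gave 6862 genes past the threshold in place of 7026.

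Genes of the NF-kB list, many of them cytokines, rose with interferon-stimulated genes, while IFNL2, IFNL3 and CXCL10 fell. Scaling shifts all genes alike, and the values argue against it as the whole cause, since the NF-kB median lay 1.69 above that of all genes (bootstrap 95% interval over genes 1.2 to 1.97). In the planned test over 4 scalings it stayed between 1.68 and 1.70, which argues against the choice among them as the cause. These scalings lay too close together to test a larger error of scale. Removing the GC and length trend left the NF-kB median at 1.68 (1.27 to 1.91, 32 genes), against that trend as the whole cause. A stronger response to transfected DNA remains possible for the rises: the median of 41 interferon-stimulated genes, without IFNL1 and CXCL10, was 0.54 (0.33 to 0.68). This value cannot decide, since the rise of these genes is part of the pattern and other activators would give it too. IFNB1 (18.7 to 9.09 CPM) and IFNL1 (17.8 to 8.87 CPM) fell as well. Such a response would not produce these falls, or those of IFNL2, IFNL3 and CXCL10, by induction, and they were not tested. RORα itself, the difference that the design names, stays open and was not tested apart from the plasmid.

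The GC and length trend, which held 0.7% of the variance and moved genes by a median of 0.0481 when removed, was too small for the fall of collagen and matrix genes: it left the 33 that fell at a median of -0.78 (-1.13 to -0.54), against -0.72 before. All 51 matrix and fibroblast genes tested, whichever way they moved, had a median of -0.43 (-0.66 to -0.21) after it and -0.39 before. A smaller share of mesenchymal cells cannot be told apart from a change within cells, because the median of VIM, THY1, CAV1, TPM2, CALD1 and S100A6 was -0.24 with an interval of -0.87 to 0.25. THY1 (-0.89) and CAV1 (-0.84) fell and VIM (0.44) rose, so these markers moved apart. RORα overexpression also stays open, untested.

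RORA rose less than 3-fold despite the plasmid. A mislabelled library is argued against by the lowest overexpression level, which was 2.27 times the highest empty vector level (counting interval 2 to 2.57). Over 4 scalings the log2 fold change of RORA stayed between 1.451 and 1.463, which argues against the choice among them as the cause. These scalings lay close together, so a larger error of scale was not tested. The share of cells transfected, loss of plasmid over the days of culture and the plasmid's isoform or untranslated regions remain possible and were not tested, since gene-level counts hold no value for them.

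Over 100 of the 126 splits of the 10 libraries into 5 and 5, the real split included, only the real one gave 7026 genes. The highest of the others gave 0, as it did for the 629 genes at 2-fold, where again 1 split gave as many. Every other split mixed the 2 groups, which widens the spread within each side and makes low counts likely from the start. The splits therefore cannot exclude chance differences between cultures, as the labels do not say whether replicates were separate cultures. For gene lists 1 split, the real one, gave 17, and the highest of the others gave 16. Leaving out single libraries gave 14 to 18 lists, so this gap does not exclude chance for the list count. The 18 splits that moved 1 library across from each group gave 10 to 16 lists and the 81 more mixed ones 0 to 8, so the high counts came from splits that still held most of the real grouping.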

How the results depend on the processing

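Leaving out EV4 and OE3 together and camera on log2(CPM + 1) were chosen only after the data were seen. Every edgeR and DESeq2 alternative, the replicate block (6950 genes past the threshold) and the pair left out (6862) gave counts within 1.5 times the reported ones, and leaving out single libraries gave 6663 to 7019 genes, 631 to 649 at 2-fold, 14 to 18 gene lists and RORA at 1.37 to 1.51 (log2). The share of called genes that were higher was 51.0%, and over the alternatives lay between 44.4% (quantile normalization) and 53.2% (limma without a filter). Genes called in both fits kept their sign in every alternative except quantile normalization, where 4845 of 4848 did. The limma alternatives change the test, the scale and the filter together, so they call fewer genes partly because fewer are tested. With a mean FPKM of at least 5 (3650 genes) limma called 2418 genes, 1187 higher and 1231 lower, the exact rank-sum test called 4278, 2219 higher and 2059 lower, and quantile normalization called 2297 higher. At 2-fold, limma on log2(FPKM + 1) called 131 genes, as it did without trend, robustly, with array weights, by rank-sum and with the block. It called 226 and 246 with pseudocounts of 0.1 and 0.01, 132 with a filter of 0.1 or none, 100 with 5, 222 as TPM, 130 by median ratio and 126 by quantile. Of the 127 named genes, 44 are not kept by the filter of 1, and the 83 kept all stayed past except by quantile, where 80 did and MT-ND1, MT-ND2 and MT-ATP6 did not. All 62 kept by the filter of 5 stayed past. In place of 17 gene lists of 36 tested, 11 of 29 passed with the filter of 5, and of 36, 9 passed with an estimated correlation, 30 with fry and 36 with fry in either direction. Over 126 single genes and 3219 settings, 3214 kept direction and side, HEPH, ANK2, MT-ND2 and MT-ATP6 were weaker in 1 each, and MT-ND1 was 0 under quantile normalization (reversed, the cause was not tested). RORA kept its call in each alternative that kept the gene (all but the filter of 5), at 0.66 to 1.47 apart from the libraries left out singly, with an adjusted p of up to 0.0178 by rank-sum. At these depths, genes with few counts carry wide intervals.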

Other observations

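The checks of row order and of the FPKM lengths and the list tests on log2(CPM + 1) were chosen only after the data were seen, and the gene lists below were fixed earlier with the others.

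Immediate early genes, the first transcripts after a stimulus, mostly rose: of 28, 20 rose, 5 fell and 3 did not pass, with the same counts adjusted over the list alone and a median of 0.55 (limma camera adjusted p = 0.000408). That call was lost at adjusted p = 0.0789 with an estimated correlation. The nuclear receptor genes NR4A2 and NR4A3 rose from 1.48 to 4.16 CPM and from 2.76 to 7.55 CPM, ATF3 from 38.9 to 103.5 CPM and KLF4 from 16.0 to 35.3 CPM. Of 32 glycolysis and hypoxia genes, 18 rose, 4 fell and 10 did not pass, with the same counts adjusted over the list alone and a median of 0.17 (camera adjusted p = 0.00452). That call too was lost, at adjusted p = 0.241 with an estimated correlation. ENO2, a neuronal enolase, rose from 48.1 to 118.5 CPM, ANGPTL4, a lipase inhibitor, from 97.8 to 240 CPM, VEGFA from 66.9 to 142 CPM and ADM from 19.7 to 41.1 CPM. Of 24 fatty acid oxidation genes, 11 rose, 3 fell and 10 did not pass, with the same counts adjusted over the list alone (median 0.12, camera adjusted p = 0.0126, and adjusted p = 0.197 with an estimated correlation). That call was lost in 4 of 25 alternative settings. Its only member that changed at least 2-fold was ANGPTL4 (log2 fold change 1.30), which is shared with the glycolysis and hypoxia list. ECI1 rose by 0.69 and PPARD by 0.35 on the log2 scale, and PPARG fell by 0.64. Of 11 WNT target genes, 6 rose, 4 fell and 1 did not pass, with the same counts adjusted over the list alone (median 0.12, camera adjusted p = 0.0499, and adjusted p = 0.135 with an estimated correlation). That call was lost in 15 of 24 alternative settings. Beside the rise of CCND2, BMP4 fell by 1.02, TCF7 by 0.91 and NOTUM by 0.74 on the log2 scale. The reported camera test of the WNT list held 5 of its 11 genes, and none of those named here.

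Of 23 heat shock genes, 9 rose, 6 fell and 8 did not pass, with the same counts adjusted over the list alone. Their median was 0.06, their mean -0.07 and camera, pointing up, gave an adjusted p of 0.768. DNAJB4 fell from 119 to 58.0 CPM and HSF2 from 34.3 to 25 CPM, CRYAB fell as given for the lens list, and HSPB8 rose from 3.70 to 5.77 CPM. Of 8 replication-dependent histone genes, most of whose transcripts lack a poly(A) tail, none rose, 7 fell and 1 did not pass, with 8 falls adjusted over the list alone and a median of -1.06. Too few were kept for the reported list test, but with the lower FPKM filter of 0.1 camera gave an adjusted p of 0.000659, down. On log2(CPM + 1) it gave 0.00114, and 0.0468 with an estimated correlation. H2BC12 fell from 16.2 to 5.22 CPM, H4C8 from 2.13 to 0.902 CPM, H1-2 from 9.48 to 4.10 CPM and H2BC5 from 6.31 to 2.72 CPM. Of 12 mitochondrially encoded genes, 5 rose, 6 fell and 1 did not pass, with the same counts adjusted over the list alone, a median of 0.02, a mean of 0.01 and camera pointing down (adjusted p = 0.644). MT-CO3 fell by 0.46, MT-ATP6 by 0.37, MT-ND2 rose by 0.44 and MT-ND1 by 0.35 on the log2 scale, except that quantile normalization gave 0 for MT-ATP6 and MT-ND1 and 0.07 for MT-ND2. Of 52 ribosomal protein genes, 24 rose, 6 fell and 22 did not pass, with the same counts adjusted over the list alone (median 0.07, camera adjusted p = 0.0499, and adjusted p = 0.6 with an estimated correlation). That call was lost in 13 of 25 alternative settings. RPS18 rose by 0.32 and RPS27 by 0.30, the latter with overlapping groups, and RPS23 fell by 0.37 and RPL22 by 0.30 on the log2 scale. With single libraries left out, the RPS27 value ran from 0.17 to 0.35. Ribosomal protein genes have many processed pseudogenes that share their reads.

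The remaining lists are given as members that rose and fell of those tested, and none of those tested by camera passed in the reported setting. They were selenium handling (4 and 2 of 9), ferroptosis and iron (10 and 9 of 28), autophagy and lysosome (15 and 5 of 38), mitophagy (5 and 7 of 18) and nuclear OXPHOS genes (3 and 8 of 39). Cholesterol synthesis had 4 and 7 of 23, fatty acid synthesis 6 and 8 of 19, the proteasome 3 and 6 of 31, YAP targets 9 and 8 of 21 and metallothioneins 2 and 0 of 3. Adjusted over the list alone, autophagy had 14 rises, mitophagy 8 falls and OXPHOS 2 rises, with the other counts in these 2 sentences the same.

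The deposited table runs in 3 stretches of ascending gene ID, of 414, 227 and 11899 genes. All 408 genes tested in the first rose at least 2-fold and all 218 in the second fell at least 2-fold, while in the third 3 of 11894 rose at least 2-fold. The gene length implied by FPKM lay within 10% of the summed exon length for 69.6% of genes and within 10% of the union of exons for 5.9%.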
